A study of Mus musculus with 22 samples.

How the data were processed

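Gene-level RNA-seq counts from the whole brains of 22 aged male C57BL/6J mice were used, in 6 groups. Per the labels' protocols, RNA with an integrity number of at least 8.5 went into poly(A)-enriched stranded libraries that were read as paired ends of 150 bp on an Illumina instrument, and the reads were aligned to GRCm38/mm10. The deposited table holds whole-number read counts per gene for each library, not normalized, as its values show. The aligner, the counting program, its strand setting and the annotation release are not given in the sources used here. Because strand handling is unknown, overlapping and antisense genes were treated as uncertain, as were genes with near-identical copies. No UMIs are mentioned in the labels, so counts are reads and not molecules, and counting error is only part of their error.

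The table lists 56748 gene identifiers with a symbol each, of which 2693 carry the identifier as their symbol, and 77 symbols are shared by more than 1 identifier. GENCODE release M21 for GRCm38 held 52073 of the identifiers. The remaining 4675 identifiers took 0.753% of the counts, kept their counts in every test and were given no coordinates. Each column of the table matched the library name of 1 sample, and 0 columns belonged to other samples. Groups and replicate numbers were taken from the sample labels.

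Library totals ran from 17.2 to 31.2 M counts, with a median of 21.6 M. A floor of 3 counts in a library corresponded to 0.0963 CPM in the deepest library and 0.175 CPM in the shallowest, and values below it were treated as not detectable. Counts were fitted with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr with the groups as design (20026 genes), library sizes were scaled by TMM, and a quasi-likelihood model with robust dispersion estimates was fitted to all 22 libraries as 6 group means. The fit had 16 residual degrees of freedom and a common biological coefficient of variation of 0.103. From it 11 contrasts were drawn: LPS against PBS in each of 3 arms, chemical exposure against control with and without LPS, CBD against vehicle in exposed mice with and without LPS, exposed CBD mice against controls with and without LPS, and 2 interactions, in which the LPS response of exposed mice was set against that of controls and that of exposed CBD mice against that of exposed vehicle mice. Tests were two-sided, with Benjamini-Hochberg adjustment over the 20026 genes and a threshold of adjusted p 0.05. The standard error of a log2 fold change was its size divided by the square root of the F statistic. Printed CPM values use the TMM-scaled library size and are given as mean ± SD over the libraries of a group.

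The contrasts, the tests, 41 gene lists, the alternatives and the rule for which genes are named were written down before the data were examined. Genes named by size were the 6 largest rises and 6 largest falls past the threshold with an average log2 CPM of at least 0 (all of them where fewer passed) in the 7 contrasts of 2 groups for LPS, exposure and CBD, and the 3 largest in each direction in the other contrasts. Where none passed, the 3 genes with the smallest p are given as values. For each list described in those 7 contrasts, the 3 members with the smallest p are named, and in the other contrasts members are named as examples chosen by the same order. A gene without a proper symbol counted, and the next gene with one was named too. Results for some genes that this rule names are not reported. Which lists are described was decided after their tests were seen, mostly those with the smallest adjusted p.

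Gene lists were tested with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01, adjusted over the 41 lists of a contrast. An estimated correlation and the self-contained test fry were run as alternatives, and the adjusted p with an estimated correlation is printed wherever it ended a call. Members past the threshold were counted over all genes tested and again adjusted over the list alone. A list score was the mean log2 CPM (prior count 2) of a list's members in a library, compared between groups by a two-sided exact permutation test. Such an exact permutation test cannot fall under p = 0.1 with 3 against 3 libraries, nor under p = 0.0286 with 4 against 4. Differences between arms in the LPS response of a score were tested by exchanging arm labels within each LPS state, over all 4900 arrangements for 4 groups of 4.

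Alternatives comprised RLE and upper-quartile scaling, no filter on low counts, a strict filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma voom with sample quality weights, a fit to the groups of a contrast alone, a block for the replicate number, 1 surrogate variable from sva 3.50.0, the choroid plexus score as a covariate, an adjusted p of 0.1, and leaving out each library in turn. Scores of olfactory bulb and cerebellar neurons as covariates, and the removal of CtrlVehLPS replicate 1 from contrasts that do not hold it, were added after the data were seen. The pipeline was tested on simulated counts with 200 genes changed by known folds. It made 0 calls when nothing was changed, but regrouped real libraries gave up to 50. For LPS in control mice, over 19641 simulated genes, it recovered 37.3% of genes changed 1.5-fold, 62.7% at 2-fold and 77.3% at 3-fold. Of 124 calls 6 were false. For LPS in exposed vehicle mice, over 19623 genes, the shares were 53.7%, 82.1% and 84.8%, with 7 of 154 false. For CBD under LPS, over 19612 genes, they were 58.2%, 76.1% and 80.3%, with 14 of 157 false. For the interaction of CBD and LPS, over 19616 genes, they were 38.8%, 61.2% and 75.8%, with 6 of 123 false.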

Results

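Gene expression was measured in the brains of 22 male mice that had received the chemicals of a Gulf War illness model, or their vehicle, as young adults and were then kept to 17.5 months of age. Exposure (GW) was 0.7 mg/kg pyridostigmine bromide, an inhibitor of acetylcholinesterase, with 200 mg/kg permethrin, an insecticide that acts on voltage-gated sodium channels, injected daily for 10 days from 10 weeks of age. Old mice then received 30 mg/kg cannabidiol (CBD), a non-intoxicating cannabinoid, daily for 28 days and every other day for 2 weeks, or vehicle. Brains were taken 24 h after 0.33 mg/kg lipopolysaccharide (LPS), the bacterial cell-wall component used to provoke systemic inflammation, or PBS. The groups were CtrlVeh (3 mice) and CtrlVehLPS (3 mice), which had no exposure, GWVeh (4) and GWVehLPS (4), which were exposed and had vehicle, and GWCBD30 (4) and GWCBD30LPS (4), which were exposed and had CBD. CBD was analysed in exposed mice only, so its effect in unexposed mice was not analysed here. The series title frames the question as neuroimmune priming by the exposure and its reversal by CBD. The comparisons below take that in turn: the LPS response in each arm, the exposure, the CBD treatment and the differences between LPS responses.

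Library totals were 17.4, 21.4 and 25.5 M counts in CtrlVeh and 27.2, 17.7 and 17.2 M in CtrlVehLPS. They were 22.1, 20.1, 24.4 and 22.6 M in GWVeh and 28.8, 26.2, 21.4 and 18.8 M in GWVehLPS. GWCBD30 had 23.4, 21.5, 21.6 and 19.5 M and GWCBD30LPS 31.2, 20.5, 26.6 and 18.2 M. Mitochondrially encoded genes took between 3.83% of the counts (GWCBD30 replicate 3) and 5.04% (GWVehLPS replicate 2). The chi-square per gene between libraries of 1 group lay between 4.08 and 22.6. Each library was counted as a separate sample, as labelled. CtrlVehLPS replicate 1 stood apart in tissue markers: its cerebellar neuron score was 2.48, against 6.18 and 6.27 in the other CtrlVehLPS libraries, and Gabra6, a receptor subunit of cerebellar granule cells, had 0 counts there. The same library held 398.5 CPM of 18 genes for pancreatic digestive enzymes, against 4.83 to 7.60 CPM in the other 21 libraries. Olfactory bulb neuron scores were 3.64, 3.01 and 2.87 in the 3 CtrlVehLPS libraries and 1.56 to 1.78 in the 3 CtrlVeh libraries. Among the other LPS libraries the score was also raised in GWVehLPS replicates 2 and 3 (2.69 and 3.14) and GWCBD30LPS replicate 4 (2.75).

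**Figure D1:**
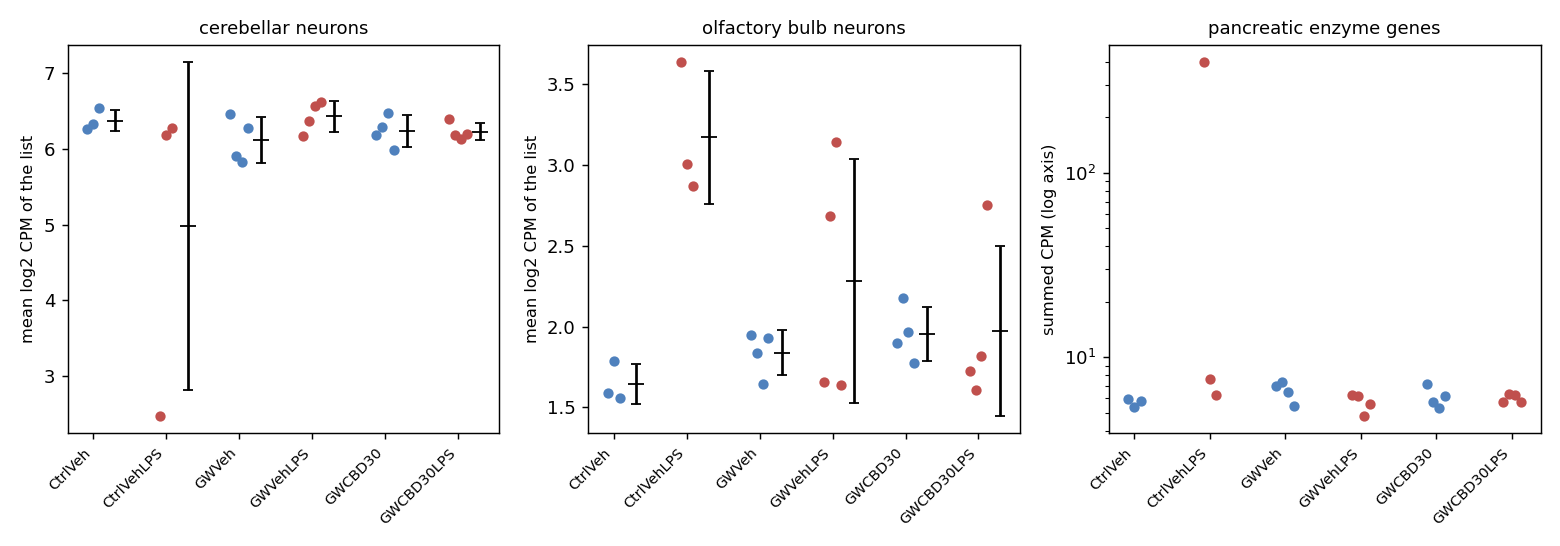
Tissue marker levels in each library by group (x axis): mean log2 CPM of the cerebellar neuron list (left) and the olfactory bulb neuron list (middle), and the summed CPM of 18 pancreatic enzyme genes on a log axis (right). Points are libraries (blue PBS, red LPS), and bars in the left and middle panels show the mean ± SD. CtrlVehLPS replicate 1 lies at 2.48 for cerebellar neurons and at 398.5 CPM for the enzymes.

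In control mice, LPS raised microglial and complement genes in the brain. Ly86 (MD-1, a partner of a Toll-like receptor family protein) went from 6.17 ± 0.476 CPM in CtrlVeh to 14.0 ± 0.102 CPM in CtrlVehLPS (SD, n = 3 each), a log2 fold change of 1.18 ± 0.17 (SE, adjusted p = 0.000122, edgeR). The C1q chains that start the classical complement cascade rose together: C1qb by 0.94 ± 0.10 (adjusted p = 4.97e-07), C1qa by 0.85 ± 0.10 (adjusted p = 1.18e-05) and C1qc by 0.89 ± 0.11 (adjusted p = 1.38e-05). Of 20026 genes, 99 passed the threshold, 83 higher and 16 lower with LPS, and 2452 had an unadjusted p under 0.05 where chance gives 1001.3.

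Homeostatic microglia genes had the smallest camera p of the 41 lists in this contrast. Of 21 members, 11 rose, 0 fell and 10 did not pass (15 rose when adjusted over the list alone), with a mean log2 fold change of 0.56 (camera adjusted p = 1.01e-28). Its members with the smallest p were the secreted protein gene Olfml3 (1.07 ± 0.13, adjusted p = 1.38e-05), the microglial surface marker Tmem119 (0.71 ± 0.10, adjusted p = 6.69e-05) and Csf1r, the receptor that microglia need for survival (0.71 ± 0.10, adjusted p = 0.000122). Complement genes rose as a list (mean 0.37, adjusted p = 1.61e-09), with 3 of 19 members higher, the C1q chains, and 6 when adjusted over the list alone. Genes of the heat shock and unfolded protein response were higher (mean 0.21, adjusted p = 5.06e-11): 6 of 27 rose, and 10 did when adjusted over the list alone. They included the endoplasmic reticulum chaperone genes Calr (0.39 ± 0.07, adjusted p = 0.00299) and Pdia4 (0.39 ± 0.08, adjusted p = 0.0183) and the transcription factor gene Xbp1 (0.36 ± 0.08, adjusted p = 0.0176). Glucocorticoid-responsive genes were higher (mean 0.32, adjusted p = 2.06e-08), with 1 of 20 past the threshold and 10 when adjusted over the list alone. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 0.56 ± 0.11 (adjusted p = 0.00729), while Sgk1 (0.87 ± 0.21, adjusted p = 0.0783) and Tsc22d3 (0.27 ± 0.07, adjusted p = 0.0797) did not pass. The list of endothelial activation and acute-phase genes was higher as a whole (mean 0.79, adjusted p = 5.89e-08), although 0 of 25 members passed over all genes and 3 did when adjusted over the list alone. Its leading members were the adhesion molecule Selp (2.77 ± 0.75, adjusted p = 0.0817), Lrg1 (1.67 ± 0.49, adjusted p = 0.124) and Ch25h (2.09 ± 0.62, adjusted p = 0.125).

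Olfactory bulb neuron genes stood higher in CtrlVehLPS than in CtrlVeh (mean 1.97, adjusted p = 9.07e-13, 4 of 13 members higher and 0 lower). Adjusted over the list alone, 10 were higher and 1 lower. Members past the threshold included Scgn, a calcium sensor of bulb interneurons (2.78 ± 0.60, adjusted p = 0.0224), Trh, the thyrotropin-releasing hormone (1.15 ± 0.20, adjusted p = 0.00396), and Meis2 (0.59 ± 0.12, adjusted p = 0.0224). Shisa3 (2.31 ± 0.47, adjusted p = 0.0240), the protease inhibitor Spint1 (1.35 ± 0.24, adjusted p = 0.00299) and the interneuron transcription factor Dlx5 (1.20 ± 0.22, adjusted p = 0.00652) were, with Scgn, Ly86 and Trh, the 6 largest rises by the naming rule. Tph2 and Slc6a4, genes of serotonin neurons that were looked at after the result was seen, were also higher in all 3 CtrlVehLPS libraries (10.6 to 18.0 and 5.58 to 13.5 CPM) than in all 3 CtrlVeh libraries (3.70 to 7.41 and 2.33 to 4.62 CPM). Neither passed (1.47 ± 0.70, adjusted p = 0.411, and 1.57 ± 0.73, adjusted p = 0.396). With olfactory bulb and cerebellar scores as covariates, a choice made after seeing the data, the bulb list had a mean of 0.02 (adjusted p = 0.832) and 32 genes passed, of which 21 were among the 99. The 6 largest falls were Angptl2 (-1.08 ± 0.24, adjusted p = 0.0244), Pla2g4e (-0.60 ± 0.14, adjusted p = 0.0462), the cold-inducible RNA-binding protein Rbm3 (-0.49 ± 0.10, adjusted p = 0.0147), the nuclear receptor Rora (-0.48 ± 0.11, adjusted p = 0.0345), Trim59 and Foxn2 (-0.46 ± 0.11 and -0.43 ± 0.10).

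Further lists passed only at the preset correlation. Cytosolic ribosomal protein genes lay higher (mean 0.19, adjusted p = 1.89e-17, and adjusted p = 0.317 with an estimated correlation), with 2 of 82 members past the threshold, Rps2 (0.37 ± 0.09, adjusted p = 0.0406) and Rpl9 (0.32 ± 0.08, adjusted p = 0.0413), and 14 when adjusted over the list alone. Rps14 (0.33 ± 0.08, adjusted p = 0.0651) did not pass. Cholesterol synthesis genes lay lower (mean -0.13, adjusted p = 4.25e-06, and 0.0940 with an estimated correlation). Of its 24 members 2 fell, and 8 did when adjusted over the list alone. These 2 were Insig1 (-0.32 ± 0.07, adjusted p = 0.0168) and Hsd17b7 (-0.42 ± 0.09, adjusted p = 0.0246). Interferon-stimulated genes had a mean of 0.30 (adjusted p = 0.000190, and 0.341 with an estimated correlation), 0 of 39 passing either way. Oas1a (1.58 ± 0.47, adjusted p = 0.134), Ifitm3 (0.63 ± 0.21, adjusted p = 0.177) and Irf7 (1.21 ± 0.40, adjusted p = 0.188) led it. Irf7 passed without CtrlVehLPS replicate 1 (1.61, adjusted p = 0.0278) and with bulb and cerebellar covariates (2.32, adjusted p = 0.00484). Cerebellar neuron genes had a mean of -0.64 (adjusted p = 4.76e-08, and 0.341 with an estimated correlation), 0 of 16 passing either way. Calb1 (-0.53 ± 0.18, adjusted p = 0.232), En2 (-0.96 ± 0.45, adjusted p = 0.410) and Itpr1 (-0.32 ± 0.16, adjusted p = 0.437) led it, and CtrlVehLPS replicate 1 lacked cerebellar transcripts.

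The 99 calls were sensitive to single libraries. Without CtrlVeh replicate 1, 2 or 3 the number was 46, 20 or 26, and without CtrlVehLPS replicate 1 it was 62. Of the 28 genes past the threshold that the naming rule picked, 7 kept their call whichever library was left out, namely Ly86, Olfml3, Tmem119, Csf1r and the C1q chains. Of these, Ly86 lost its call with bulb and cerebellar scores as covariates (0.98, adjusted p = 0.0889).

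In exposed mice given vehicle, LPS raised microglial, complement, interferon-stimulated and endothelial genes. C1qb rose by 0.99 ± 0.08 (adjusted p = 2.32e-09), from 36.0 ± 2.20 CPM in GWVeh to 71.5 ± 3.70 CPM in GWVehLPS (SD, n = 4 each). Icam1, an endothelial adhesion molecule for leukocytes, rose by 1.31 ± 0.21 (adjusted p = 0.000317), from 1.98 ± 0.314 to 4.91 ± 0.612 CPM. Lcn2, an acute-phase iron-binding protein, had the largest rise by the naming rule, 3.45 ± 0.74 (adjusted p = 0.0313). Its call was lost without GWVeh replicate 2, 3 or 4 or GWVehLPS replicate 1 or 4 (adjusted p from 0.0793 to 0.116). In all 188 genes passed, 166 higher and 22 lower, with 2081 at an unadjusted p under 0.05. Of the 166 higher genes, 32 were among the 83 higher in control mice, where 0.688 would be shared by independent lists. No library is common to these contrasts.

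Homeostatic microglia genes rose in 13 of 21 members and fell in 0 (16 rose adjusted over the list alone), with a mean of 0.57 (adjusted p = 2.72e-42). Olfml3 (1.0 ± 0.11, adjusted p = 1.07e-06) and Csf1r (0.69 ± 0.08, adjusted p = 7.89e-06) were among them. Activated and disease-associated microglia genes were higher (mean 0.37, adjusted p = 2.53e-14), with 5 of 28 members past the threshold and 9 adjusted over the list alone, among them the Fc receptors Fcgr3 (1.16 ± 0.13, adjusted p = 8.48e-07) and Fcgr2b (1.06 ± 0.17, adjusted p = 0.000409) and the adaptor Tyrobp (0.87 ± 0.13, adjusted p = 0.000157). Complement genes rose in 7 of 19 members (10 adjusted over the list alone, mean 0.56, adjusted p = 3.98e-28), led by C1qb, C1qa (0.93 ± 0.09, adjusted p = 3.16e-08) and C1qc (0.86 ± 0.09, adjusted p = 7.47e-07). Border-associated macrophage genes were higher (mean 0.29, adjusted p = 0.00429), with the scavenger receptor Stab1 past the threshold (0.68 ± 0.12, adjusted p = 0.000702), 1 of 11, and 3 adjusted over the list alone. Cbr2 (1.28 ± 0.37, adjusted p = 0.105) and F13a1 (0.67 ± 0.23, adjusted p = 0.218) did not pass. Other named rises were Plin4, a lipid droplet coat protein (1.97 ± 0.33, adjusted p = 0.00412), and the myeloid genes Abi3 (1.55 ± 0.36, adjusted p = 0.0215), C5ar1 (1.5 ± 0.37, adjusted p = 0.0322) and Ms4a6d (1.5 ± 0.32, adjusted p = 0.0107).

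Interferon-stimulated genes rose in 9 of 39 members, 23 adjusted over the list alone, and all 39 had positive fold changes (mean 0.74, adjusted p = 2.07e-31). The antiviral membrane protein Ifitm3 (1.30 ± 0.17, adjusted p = 6.62e-05), the transcription factor Irf7 (1.47 ± 0.33, adjusted p = 0.0215) and Trim30a (0.94 ± 0.22, adjusted p = 0.0215) led it. Endothelial activation and acute-phase genes rose in 7 of 25 members and in 18 adjusted over the list alone (mean 1.19, adjusted p = 2.85e-26). Beside Icam1 they included the acute-phase gene Saa3, with 141 counts over GWVehLPS and 2 over GWVeh, a ratio of 66.2 with a 95% exact counting interval of 18.0 to 552 (adjusted p = 0.000702), and E-selectin, Sele (3.95 ± 0.76, adjusted p = 0.00287). Endothelial identity genes rose in 4 of 21 members, 9 adjusted over the list alone (mean 0.36, adjusted p = 1.19e-12). Ly6c1 (1.09 ± 0.14, adjusted p = 2.57e-05), Ly6a (1.37 ± 0.19, adjusted p = 0.000352) and the junction protein Pecam1 (0.69 ± 0.13, adjusted p = 0.00409) were in front. Reactive astrocyte genes rose in 3 of 35 members, 12 adjusted over the list alone (mean 0.49, adjusted p = 1.19e-12): Fbln5 (1.07 ± 0.19, adjusted p = 0.00556), ceruloplasmin, Cp (0.55 ± 0.12, adjusted p = 0.00888), and Lcn2. Inflammatory cytokine, chemokine and NF-kB target genes were higher as a list (mean 0.54, adjusted p = 2.89e-06), with 1 of 21 past the threshold and 3 adjusted over the list alone. That gene was the monocyte chemokine Ccl12 (2.18 ± 0.51, adjusted p = 0.0215), while the LPS receptor Tlr4 (0.90 ± 0.28, adjusted p = 0.139) and Nfkb2 (0.64 ± 0.21, adjusted p = 0.180) did not pass.

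Glucocorticoid-responsive genes rose in 6 of 20 members, 9 adjusted over the list alone (mean 0.42, adjusted p = 6.19e-15), among them Fam107a (0.78 ± 0.10, adjusted p = 0.000116), Sult1a1 (1.27 ± 0.20, adjusted p = 0.000702) and Tsc22d3, which encodes the anti-inflammatory protein GILZ (0.34 ± 0.06, adjusted p = 0.00225). Heat shock and unfolded protein response genes rose in 3 of 27 members and in 12 adjusted over the list alone (mean 0.17, adjusted p = 1.77e-08), namely Pdia4 (0.29 ± 0.07, adjusted p = 0.0319), Manf (0.30 ± 0.07, adjusted p = 0.0385) and Sdf2l1 (0.57 ± 0.14, adjusted p = 0.0434). Genes of cell cycle arrest and senescence rose in 2 of 16 members, 4 adjusted over the list alone (mean 0.22, adjusted p = 0.00185): Igfbp7 (0.85 ± 0.14, adjusted p = 0.000471) and the cyclin-dependent kinase inhibitor Cdkn1a (0.56 ± 0.11, adjusted p = 0.00269), with Plaur at 1.37 ± 0.48 (adjusted p = 0.215). Cholesterol synthesis genes fell in 4 of 24 members, 16 adjusted over the list alone (mean -0.24, adjusted p = 1.07e-15). Msmo1 (-0.31 ± 0.07, adjusted p = 0.0142) and Hmgcs1 (-0.34 ± 0.08, adjusted p = 0.0186) were among them. The 6 largest falls were Opalin, a myelin protein gene (-1.03 ± 0.21, adjusted p = 0.0153), the predicted genes Gm48583 (-0.93 ± 0.22) and Gm19410 (-0.67 ± 0.13), the collagen gene Col5a1 (-0.63 ± 0.09, adjusted p = 0.000110), the helicase gene Blm (-0.56 ± 0.14, adjusted p = 0.0476) and Ltbp4 (-0.47 ± 0.11, adjusted p = 0.0350). The next genes with a symbol were Col6a1 (-0.47 ± 0.10, adjusted p = 0.0153) and Col6a2 (-0.42 ± 0.10, adjusted p = 0.0339).

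Olfactory bulb neuron genes had a mean of 0.85 in this contrast (adjusted p = 0.00730, and adjusted p = 0.423 with an estimated correlation), with 0 of 13 past the threshold either way. Eomes had 0.83 ± 0.32 (adjusted p = 0.321), the olfactory marker protein Omp 1.87 ± 0.76 (adjusted p = 0.380) and S100a5 77 counts over GWVehLPS and 2 over GWVeh, a ratio of 36.1 with a 95% exact counting interval of 9.67 to 304 (adjusted p = 0.400). Without GWVehLPS replicate 2 or 3, the libraries with raised bulb scores, the list gave adjusted p = 0.0965 or 0.246. Red blood cell genes had a mean of -1.04 (adjusted p = 0.000349, and adjusted p = 0.254 with an estimated correlation), with 0 of 7 past the threshold and 5 lower when adjusted over the list alone. Hba-a2 (-1.43 ± 0.50, adjusted p = 0.263), Bpgm (-0.19 ± 0.07, adjusted p = 0.277) and Hbb-bt (-1.51 ± 0.54, adjusted p = 0.285) led them. Without GWVeh replicate 1, whose red blood cell score was 5.59 against 3.23 to 3.84 in the other GWVeh libraries, the mean was -0.21 (adjusted p = 0.120). The 188 calls became 125 without GWVeh replicate 3 and also 125 without GWVeh replicate 4. Of the 46 genes past the threshold that the naming rule picked, 26 kept their call whichever library was left out.

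In exposed mice given CBD, 1 gene passed the threshold for LPS against PBS. Tsc22d3 rose by 0.38 ± 0.06 (adjusted p = 0.0167), from 52.8 ± 2.13 to 68.9 ± 5.38 CPM (SD, n = 4 each), and it was also among the genes raised in exposed vehicle mice. Unadjusted p fell under 0.05 for 1647 genes. DESeq2 called 38 genes and limma voom 87, each including Tsc22d3, and the call was lost without GWCBD30 replicate 1 or 3 or GWCBD30LPS replicate 2 or 4 and the count rose to 13 without CtrlVehLPS replicate 1, a library outside this contrast whose removal also changed the number of genes tested to 20601.

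Of 41 lists, 14 passed at the preset correlation and 0 with an estimated one. Homeostatic microglia genes had a mean of 0.24 (adjusted p = 9.77e-10, and adjusted p = 0.0525 with an estimated correlation), with 0 of 21 members past the threshold and 4 adjusted over the list alone. Csf1r had 0.37 ± 0.08 (adjusted p = 0.118), Sall1 0.33 ± 0.10 (adjusted p = 0.377) and the fractalkine receptor Cx3cr1 0.30 ± 0.10 (adjusted p = 0.404). Complement genes had a mean of 0.15 (adjusted p = 0.000964, and adjusted p = 0.155 with an estimated correlation), with 0 of 19 past the threshold and 4 adjusted over the list alone. C1qb stood at 0.43 ± 0.08 (adjusted p = 0.0580), Clu at 0.22 ± 0.07 (adjusted p = 0.369) and C1qa at 0.27 ± 0.09 (adjusted p = 0.409). Glucocorticoid-responsive genes had a mean of 0.17 (adjusted p = 2.94e-05, and adjusted p = 0.119 with an estimated correlation), with Tsc22d3 past the threshold, 1 of 20, and 2 adjusted over the list alone. Fam107a (0.34 ± 0.10, adjusted p = 0.394) and the metallothionein Mt1 (0.32 ± 0.13, adjusted p = 0.536) came next. Astrocyte identity genes had a mean of 0.17 (adjusted p = 7.14e-12, and adjusted p = 0.0525 with an estimated correlation), 0 of 19 and 7 adjusted over the list alone, with Glul at 0.25 ± 0.07 (adjusted p = 0.269) and Acsbg1 at 0.24 ± 0.07 (adjusted p = 0.355). Oligodendrocyte and myelin genes had a mean of 0.18 (adjusted p = 9.77e-10, and adjusted p = 0.155 with an estimated correlation), 0 of 23 and 3 adjusted over the list alone. Cldn11 (0.31 ± 0.08, adjusted p = 0.184), Fa2h (0.34 ± 0.09, adjusted p = 0.184) and Mobp (0.34 ± 0.11, adjusted p = 0.409) were in front. Circadian clock genes had a mean of 0.11 (adjusted p = 2.45e-05, and adjusted p = 0.0525 with an estimated correlation), 0 of 18 and 6 adjusted over the list alone. Per2 (0.34 ± 0.09, adjusted p = 0.208), Hlf (0.17 ± 0.05, adjusted p = 0.403) and Dbp (0.27 ± 0.09, adjusted p = 0.416) were in front.

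**Figure D2:**
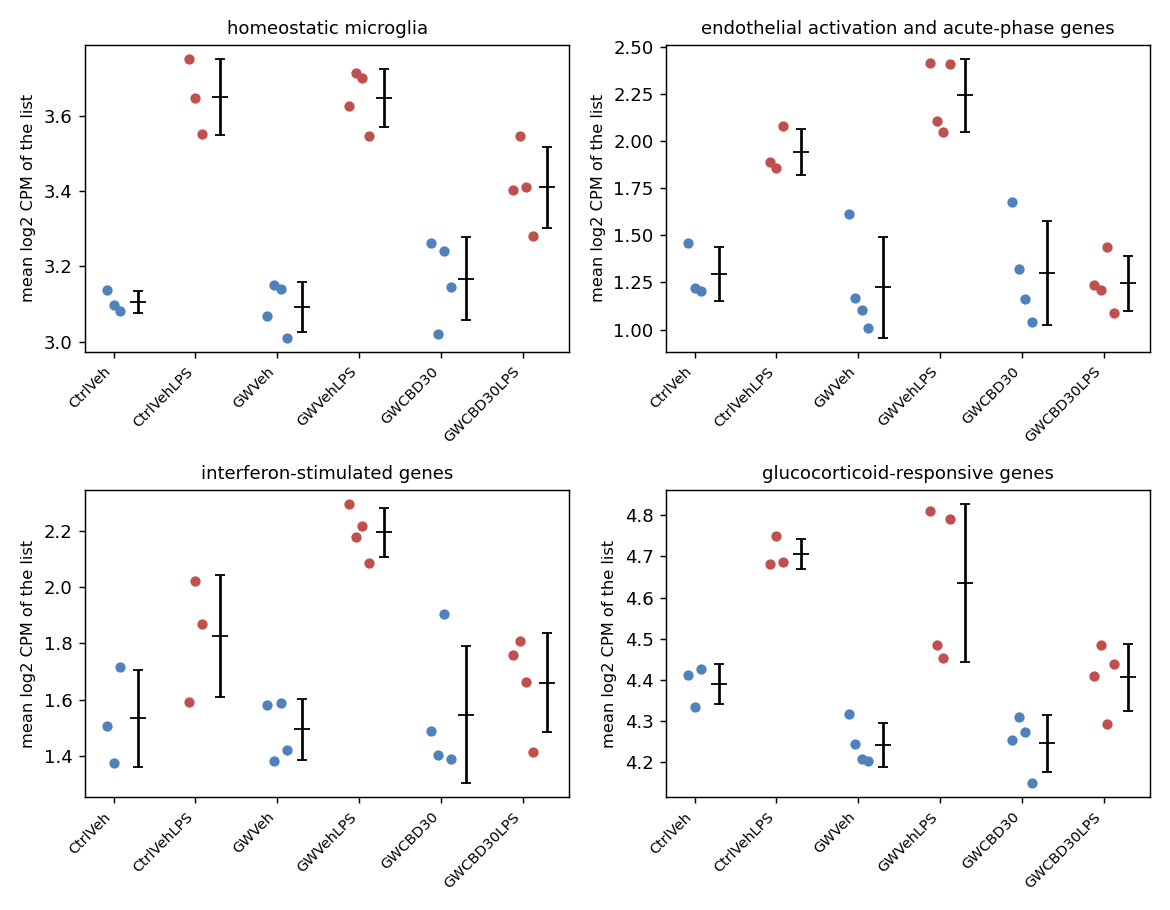
List scores (y axis, mean log2 CPM of the list's members) in each library by group (x axis) for homeostatic microglia, endothelial activation and acute-phase, interferon-stimulated and glucocorticoid-responsive genes. Points are libraries (blue PBS, red LPS) and bars show the mean ± SD; the homeostatic microglia score was 3.65 ± 0.0773 in GWVehLPS and 3.41 ± 0.109 in GWCBD30LPS.

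Chemical exposure without LPS left no gene past the threshold (GWVeh against CtrlVeh). The edgeR count was 0, with 1762 genes at an unadjusted p under 0.05, against 6 by DESeq2 and 176 by limma voom. It was 1 without CtrlVeh replicate 2 and 12 without GWVeh replicate 4. The genes with the smallest p were Arl5b (-0.52 ± 0.10, adjusted p = 0.114), the huntingtin-associated protein Hap1 (0.42 ± 0.08, adjusted p = 0.114) and the AP-1 member Fosl2 (-0.53 ± 0.11, adjusted p = 0.174).

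No list held with an estimated correlation in that contrast. Immediate-early genes had a mean of -0.17 (adjusted p = 0.000714, and adjusted p = 0.793 with an estimated correlation), with 0 of 22 past the threshold and 3 lower adjusted over the list alone. Beside Fosl2 its leading members were Nr4a3 (-0.71 ± 0.16, adjusted p = 0.317) and Nr4a2 (-0.32 ± 0.10, adjusted p = 0.441), and without CtrlVeh replicate 2 the mean was -0.08 (adjusted p = 0.0807). Glucocorticoid-responsive genes had a mean of -0.15 (adjusted p = 0.00222, and adjusted p = 0.747 with an estimated correlation), 0 of 20 either way. Tsc22d3 (-0.21 ± 0.07, adjusted p = 0.441), Per1 (-0.24 ± 0.08, adjusted p = 0.446) and Klf9 (-0.19 ± 0.07, adjusted p = 0.456) were in front. Ribosomal protein genes had a mean of 0.13 (adjusted p = 4.23e-14, and adjusted p = 0.793 with an estimated correlation), 0 of 82 and 5 adjusted over the list alone. Rps2 (0.33 ± 0.08, adjusted p = 0.390) and Rpl13 (0.28 ± 0.08, adjusted p = 0.390) led it. Thalamic and hypothalamic neuron genes had a mean of 0.44 (adjusted p = 0.000114, and adjusted p = 0.747 with an estimated correlation), 0 of 18 and 1 adjusted over the list alone. Trh (0.87 ± 0.19, adjusted p = 0.290), Sim1 (1.20 ± 0.42, adjusted p = 0.450) and Otp (1.01 ± 0.37, adjusted p = 0.459) led it. For the systems that the chemicals act on, cholinergic signalling genes had a mean of 0.11 (adjusted p = 0.0711) and 0 of 23 passed either way. Chrna2 (0.87 ± 0.35, adjusted p = 0.499), Chrna4 (0.19 ± 0.08, adjusted p = 0.510) and Pebp1 (0.18 ± 0.08, adjusted p = 0.552) led them, and the list's adjusted p was 0.0373 without CtrlVeh replicate 2, 0.0266 without GWVeh replicate 1 and 0.0413 without GWVeh replicate 4. Voltage-gated sodium channel genes had a mean of 0.04 while the test pointed down (adjusted p = 0.996), and 0 of 12 passed either way, with Scn1a at -0.15 ± 0.07 (adjusted p = 0.516) and Scn2a at -0.15 ± 0.07 (adjusted p = 0.568).

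Under LPS, exposed and control mice differed in 1 gene (GWVehLPS against CtrlVehLPS). Sox9, an astrocyte transcription factor, was higher by 0.49 ± 0.08 (adjusted p = 0.0283), at 39.9 ± 3.45 CPM in GWVehLPS (SD, n = 4) and 28.5 ± 0.415 CPM in CtrlVehLPS (SD, n = 3). At an unadjusted p under 0.05 there were 1548 genes, and DESeq2 called 25 and limma voom 5. Without CtrlVehLPS replicate 1 or 2, or GWVehLPS replicate 2 or 3, the count was 0, without CtrlVehLPS replicate 3 it was 24, and without GWVehLPS replicate 1 or 4 it was 6 or 3. With the choroid plexus score as a covariate, or the bulb and cerebellar scores, it was 0.

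The lists that separated these groups at the preset correlation included those of brain regions in which CtrlVehLPS stood apart, and none held with an estimated one. Cerebellar neuron genes had a mean of 0.69 (adjusted p = 1.53e-12, and adjusted p = 0.228 with an estimated correlation), 0 of 16 either way. Calb1 (0.51 ± 0.17, adjusted p = 0.471), Itpr1 (0.32 ± 0.15, adjusted p = 0.644) and En2 (0.92 ± 0.43, adjusted p = 0.644) were in front. Olfactory bulb neuron genes had a mean of -0.75 (adjusted p = 1.01e-05, and adjusted p = 0.228 with an estimated correlation), 0 of 13 and 1 lower adjusted over the list alone. Meis2 (-0.41 ± 0.11, adjusted p = 0.380), Cdhr1 (-1.11 ± 0.36, adjusted p = 0.466) and Doc2g (-1.23 ± 0.45, adjusted p = 0.507) were in front. Choroid plexus genes had a mean of 0.49 (adjusted p = 4.68e-11, and adjusted p = 0.228 with an estimated correlation), 0 of 21 and 4 adjusted over the list alone. Cldn2 (0.83 ± 0.27, adjusted p = 0.461), Kcnj13 (0.79 ± 0.28, adjusted p = 0.473) and Car12 (0.41 ± 0.14, adjusted p = 0.474) led it. Interferon-stimulated genes had a mean of 0.39 (adjusted p = 4.16e-10, and adjusted p = 0.228 with an estimated correlation), 0 of 39 and 2 adjusted over the list alone. The chemokine Cxcl10 (1.67 ± 0.46, adjusted p = 0.332), Ifitm3 (0.64 ± 0.18, adjusted p = 0.410) and Oasl2 (0.55 ± 0.19, adjusted p = 0.461) led it. Activated microglia genes had a mean of 0.29 (adjusted p = 4.77e-07, and adjusted p = 0.236 with an estimated correlation), 0 of 28 and 2 adjusted over the list alone. Cd68 (0.56 ± 0.17, adjusted p = 0.410), B2m (0.27 ± 0.08, adjusted p = 0.428) and Ctsz (0.23 ± 0.09, adjusted p = 0.482) led it. Mitochondrially encoded transcripts had a mean of 0.40 (adjusted p = 1.06e-08, and adjusted p = 0.228 with an estimated correlation), 0 of 13 and 5 adjusted over the list alone. mt-Nd6 (0.53 ± 0.10, adjusted p = 0.0737), mt-Nd5 (0.39 ± 0.08, adjusted p = 0.0789) and mt-Nd1 (0.23 ± 0.08, adjusted p = 0.461) led it.

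Whether exposure altered the LPS response was tested as an interaction, and 0 genes passed by edgeR, with 1688 at an unadjusted p under 0.05, 28 by DESeq2 and 0 by limma voom. The count was 1 without CtrlVeh replicate 2 or GWVehLPS replicate 2 and 3 without CtrlVehLPS replicate 3. The endothelial receptor gene Adgrl4 (0.92 ± 0.18, adjusted p = 0.247), Cntnap3 (-1.0 ± 0.21, adjusted p = 0.247) and Cpne6 (-0.44 ± 0.10, adjusted p = 0.247) had the smallest p. Interferon-stimulated genes had a mean difference of 0.44 between LPS responses (adjusted p = 5.49e-06, and 0.330 with an estimated correlation). Of 39 members, 0 passed and 1 did over the list alone, Cxcl10 (2.27 ± 0.64, adjusted p = 0.299 over all genes). With bulb and cerebellar scores as covariates the mean was 0.17 (adjusted p = 0.409). The same adjusted p of 0.330 with an estimated correlation applied to cerebellar neuron genes (mean 0.94, adjusted p = 1.43e-10), olfactory bulb neuron genes (mean -1.12, adjusted p = 4.01e-05) and ribosomal protein genes (mean -0.22, adjusted p = 1.59e-15). Of these, 0 members passed over all genes, and 0 of 16, 2 of 13 and 0 of 82 over the list alone. The exact permutation test of the interferon score gave a larger rise in exposed mice by 0.41 (p = 0.0408, Benjamini-Hochberg adjusted 0.364 over 41 lists).

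CBD without LPS left no gene past the threshold (GWCBD30 against GWVeh). The count was 0 by edgeR, DESeq2 and limma voom alike, with 1288 genes at an unadjusted p under 0.05, and 0 in each fit that left out 1 library. Gm49223 (2.01 ± 0.47), Ankrd53 (0.92 ± 0.21) and Gm45671 (-2.56 ± 0.61) had the smallest p, each with an adjusted p of 0.752. Oligodendrocyte and myelin genes had a mean of -0.20 (adjusted p = 7.85e-12, and adjusted p = 0.413 with an estimated correlation), 0 of 23 and 5 lower adjusted over the list alone. The transcription factor Olig1 (-0.28 ± 0.08), Cldn11 (-0.23 ± 0.08) and Fa2h (-0.25 ± 0.09) led it. Ribosomal protein genes had a mean of -0.14 (adjusted p = 2.51e-20, and adjusted p = 0.515 with an estimated correlation), 0 of 82 either way. Rpl32 (-0.26 ± 0.08), Rps9 (-0.22 ± 0.07) and Rps2 (-0.22 ± 0.08) led it. Nuclear-encoded oxidative phosphorylation genes had a mean of -0.09 (adjusted p = 1.17e-12, and adjusted p = 0.534 with an estimated correlation), 0 of 75 either way. Cox4i1 (-0.19 ± 0.07), Sdhc (-0.16 ± 0.07) and Ndufv1 (-0.15 ± 0.06) led it. Each of these 9 genes had an adjusted p of 0.752. The endocannabinoid system and cannabidiol target genes had a mean of -0.03 (adjusted p = 0.324) and 0 of 28 passed either way, with Abhd4 at -0.17 ± 0.09 (adjusted p = 0.758), Gpr6 at -0.30 ± 0.16 (adjusted p = 0.761) and Naaa at -0.14 ± 0.10 (adjusted p = 0.784).

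Under LPS, exposed mice given CBD had lower levels of endothelial, complement and interferon-stimulated genes than exposed mice given vehicle (GWCBD30LPS against GWVehLPS). Icam1 was lower by a log2 fold change of -1.54 ± 0.21 (adjusted p = 0.000121), at 1.68 ± 0.162 CPM with CBD and 4.91 ± 0.612 CPM with vehicle (SD, n = 4 each). Lcn2 was at 0.594 ± 0.133 CPM with CBD and 11.7 ± 6.42 CPM with vehicle (-4.27 ± 0.79, adjusted p = 0.0339). The Lcn2 call was lost without GWVehLPS replicate 1 or 4 or any 1 of the GWCBD30LPS libraries (adjusted p from 0.0729 to 0.153). In all 48 genes passed, 45 lower and 3 higher with CBD, and 1422 had an unadjusted p under 0.05. Of the 45 lower genes, 14 were among the 83 raised by LPS in control mice, a contrast with no shared library, where independent lists would share 0.187; they include C1qa, C1qb, C1qc, Ly86, Olfml3 and Tmem119. Of the 166 genes raised by LPS in exposed vehicle mice 39 were among the 45, but both contrasts use the GWVehLPS libraries, so the chance values of those libraries enter both.

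The list of endothelial activation and acute-phase genes had the smallest p of the lists. Of 25 members 7 fell, 16 adjusted over the list alone, with a mean of -1.21 (adjusted p = 7.41e-32). Beside Icam1 these were led by E-selectin, Sele, and P-selectin, Selp, which let leukocytes roll on activated vessels. Sele had 87 counts over GWVehLPS and 2 over GWCBD30LPS, a ratio of 43.9 with a 95% exact counting interval of 11.8 to 368, and Selp had 62 counts and 1, a ratio of 62.6 with an interval of 10.8 to 2512 (adjusted p = 0.00129 for both). At such counts the fitted fold change depends on the prior count. Endothelial identity genes fell in 4 of 21 members, 5 adjusted over the list alone (mean -0.27, adjusted p = 1.34e-09). Ly6c1 (-0.99 ± 0.14, adjusted p = 0.000267), Pecam1 (-0.82 ± 0.14, adjusted p = 0.00129) and Ly6a (-1.19 ± 0.19, adjusted p = 0.00337) were in front. Cd93 (-1.25 ± 0.20, adjusted p = 0.00115), a receptor of endothelial and myeloid cells, Angptl4 (-1.24 ± 0.23, adjusted p = 0.00525), an inhibitor of lipoprotein lipase, and Pglyrp1 (-1.20 ± 0.19, adjusted p = 0.000926), which binds bacterial peptidoglycan, were, with Lcn2, Icam1 and Ly6a, the 6 largest falls by the naming rule.

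Complement genes fell in 4 of 19 members, 7 adjusted over the list alone (mean -0.41, adjusted p = 2.31e-18), with C1qa (-0.66 ± 0.09), C1qb (-0.58 ± 0.08) and C1qc (-0.55 ± 0.09, adjusted p = 0.00173) in front, the first pair at adjusted p = 0.000121. Homeostatic microglia genes fell in 3 of 21 members, 9 adjusted over the list alone (mean -0.25, adjusted p = 1.05e-12): Olfml3 (-0.81 ± 0.11, adjusted p = 0.000121), Fcrls (-0.72 ± 0.14, adjusted p = 0.00830) and Tmem119 (-0.37 ± 0.08, adjusted p = 0.0375). Interferon-stimulated genes fell in 2 of 39 members and 17 adjusted over the list alone, and 0 of the 39 had a positive fold change (mean -0.55, adjusted p = 6.22e-23). Ifitm3 (-1.02 ± 0.17, adjusted p = 0.00233) and Oasl2 (-0.79 ± 0.17, adjusted p = 0.0352) passed, and Zbp1, a sensor of nucleic acids, stood at -2.22 ± 0.56 (adjusted p = 0.102). Reactive astrocyte genes fell in 2 of 35 members, Cp (-0.70 ± 0.12, adjusted p = 0.00137) and Lcn2, and in 11 adjusted over the list alone (mean -0.51, adjusted p = 3.12e-16), with Fbln5 at -0.89 ± 0.19 (adjusted p = 0.0570). Inflammatory cytokine, chemokine and NF-kB target genes were lower as a list (mean -0.46, adjusted p = 1.30e-05) with 0 of 21 past the threshold and 2 adjusted over the list alone. Bcl3 (-1.84 ± 0.43, adjusted p = 0.0562), Ccl12 (-1.85 ± 0.49, adjusted p = 0.120) and Nfkb2 (-0.60 ± 0.21, adjusted p = 0.395) led it. Border-associated macrophage genes were lower (mean -0.43, adjusted p = 5.77e-05) with 0 of 11 past the threshold and 2 adjusted over the list alone. Stab1 (-0.48 ± 0.12, adjusted p = 0.0679), F13a1 (-0.93 ± 0.24, adjusted p = 0.106) and Cbr2 (-0.94 ± 0.36, adjusted p = 0.499) led it. Activated microglia genes lay lower (mean -0.28, adjusted p = 1.47e-09, and adjusted p = 0.0969 with an estimated correlation), with Fcgr3 (-0.92 ± 0.13, adjusted p = 0.000121), Fcgr2b (-1.09 ± 0.17, adjusted p = 0.000825) and B2m (-0.36 ± 0.08, adjusted p = 0.0284) past the threshold, 3 of 28, and 7 adjusted over the list alone.

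Heat shock and unfolded protein response genes fell in 4 of 27 members, 11 adjusted over the list alone (mean -0.18, adjusted p = 1.05e-12). Pdia4 (-0.33 ± 0.07, adjusted p = 0.0339), Sdf2l1 (-0.66 ± 0.14, adjusted p = 0.0343) and Calr (-0.26 ± 0.06, adjusted p = 0.0395) were in front. Cholesterol synthesis genes went the other way (mean 0.18, adjusted p = 1.36e-11), with 1 of 24 higher and 7 adjusted over the list alone. Hmgcs1 (0.28 ± 0.08, adjusted p = 0.188) did not pass. Genes higher with CBD included the cold-inducible Rbm3 (0.40 ± 0.09, adjusted p = 0.0339) and the microRNA host transcript Mir22hg (0.49 ± 0.11, adjusted p = 0.0480). Endocannabinoid system and cannabidiol target genes had a mean of 0.01 (adjusted p = 0.219) with 0 of 28 past the threshold either way. Gpr3 (0.43 ± 0.15, adjusted p = 0.412), the cannabinoid receptor Cnr2 (-1.25 ± 0.55, adjusted p = 0.628) and the adenosine receptor Adora2a (0.21 ± 0.10, adjusted p = 0.653) led it. The list's adjusted p was 0.0490 without GWVehLPS replicate 2. Red blood cell genes were higher as a list (mean 0.65, adjusted p = 0.000810, and adjusted p = 0.2998 with an estimated correlation), with 0 of 7 past the threshold either way. Hba-a2 (1.20 ± 0.50, adjusted p = 0.624), Hbb-bt (1.04 ± 0.55, adjusted p = 0.752) and Hbb-bs (0.75 ± 0.44, adjusted p = 0.796) led them. The list's score was higher by 0.67 in GWCBD30LPS, with all 4 libraries above all 4 of GWVehLPS (exact permutation p = 0.0286, Benjamini-Hochberg adjusted p = 0.0901). The 48 calls became 28 without GWVehLPS replicate 1, 24 without GWCBD30LPS replicate 1 and 22 without GWCBD30LPS replicate 4, and 16 of the 28 genes past the threshold that the naming rule picked kept their call whichever library was left out. With bulb and cerebellar scores as covariates 80 genes passed, including all 48, and with the choroid plexus score 33 passed, including 31 of the 48.

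**Figure D3:**
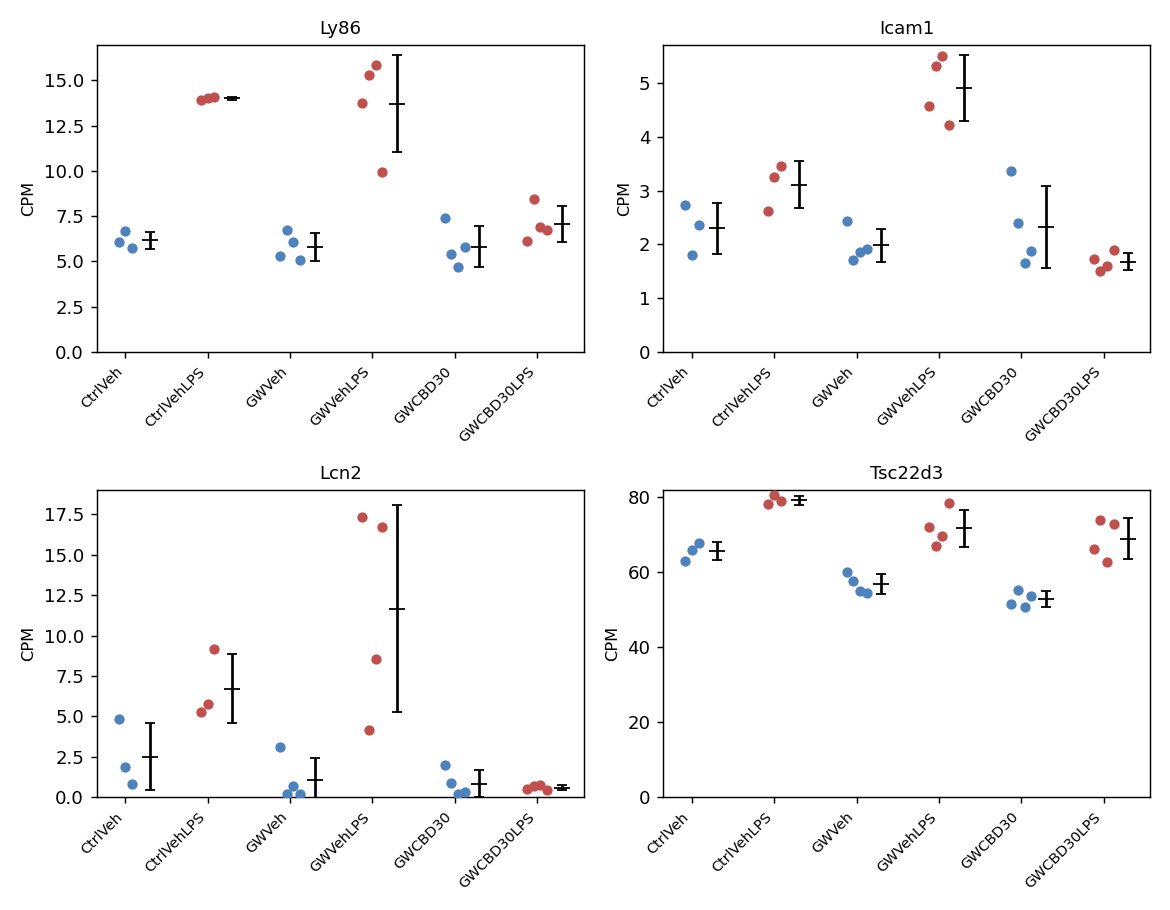
Counts per M (y axis) of Ly86, Icam1, Lcn2 and Tsc22d3 in each library by group (x axis). Points are libraries (blue PBS, red LPS) and bars show the mean ± SD; Icam1 was 4.91 ± 0.612 CPM in GWVehLPS and 1.68 ± 0.162 CPM in GWCBD30LPS, and Tsc22d3 was 71.7 ± 4.92 and 68.9 ± 5.38 CPM.

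The difference between the LPS responses of exposed CBD mice and exposed vehicle mice was itself tested, and 9 genes had a smaller response with CBD while 0 had a larger one. They were Icam1 (-1.78 ± 0.30, adjusted p = 0.00904), Cd93 (-1.51 ± 0.29, adjusted p = 0.0363), the Fc receptor Fcgr4 (-4.69 ± 0.89, adjusted p = 0.0293), Fcgr3 (-1.17 ± 0.18, adjusted p = 0.00612), Adgrl4 (-1.02 ± 0.17, adjusted p = 0.00734), Pglyrp1 (-1.39 ± 0.28, adjusted p = 0.0471), Ifitm3 (-1.29 ± 0.25, adjusted p = 0.0402), Olfml3 (-0.85 ± 0.16, adjusted p = 0.0293) and C1qa (-0.66 ± 0.12, adjusted p = 0.0293). Fcgr4 averaged 0.117 to 1.04 CPM over the groups of this contrast. At an unadjusted p under 0.05 there were 1140 genes.

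As lists, endothelial activation and acute-phase genes (mean -1.37, adjusted p = 2.36e-21, 1 of 25 lower and 12 adjusted over the list alone), interferon-stimulated genes (mean -0.62, adjusted p = 1.91e-16, 1 of 39 either way) and homeostatic microglia genes (mean -0.33, adjusted p = 6.77e-11, 1 of 21 and 9 adjusted over the list alone) had a smaller LPS response with CBD. So did complement genes (mean -0.41, adjusted p = 6.77e-11, 1 of 19 and 6 adjusted over the list alone), cytokine and NF-kB target genes (mean -0.62, adjusted p = 5.63e-06, 0 of 21 and 5 adjusted over the list alone) and border-associated macrophage genes (mean -0.46, adjusted p = 0.000144, 0 of 11 and 2 adjusted over the list alone). Cholesterol synthesis genes, which fell with LPS in vehicle mice, differed in the other direction (mean 0.21, adjusted p = 8.81e-10, 0 of 24 either way). Each of these 7 lists held with an estimated correlation. Red blood cell genes, which also differed in the other direction, did not (mean 1.29, adjusted p = 5.95e-06, and adjusted p = 0.174 with an estimated correlation, 0 of 7 either way). Their mean was 0.46 without GWVeh replicate 1, and the difference of their score was 1.09 (exact permutation p = 0.107). In the exact permutation tests of the scores, the LPS rise with CBD was lower by -1.08 for endothelial activation (p = 0.00939), by -0.31 for homeostatic microglia (p = 0.00898) and by -0.58 for interferon-stimulated genes (p = 0.0143), over 4900 arrangements. The Benjamini-Hochberg adjusted values over 41 lists were 0.0962, 0.0962 and 0.0976. The 9 calls became 2 without GWCBD30 replicate 1, 3 without GWVeh replicate 2, GWVehLPS replicate 1, GWCBD30 replicate 2 or GWCBD30LPS replicate 4, 4 without GWVeh replicate 4 and 5 without GWVeh replicate 3. They became 14 without GWCBD30LPS replicate 2 and 17 without GWVehLPS replicate 2 or CtrlVehLPS replicate 1. Without GWCBD30 replicate 1 both genes that passed were among the 9.

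Exposed mice given CBD and LPS also had lower LPS-responsive genes than unexposed mice given LPS (GWCBD30LPS against CtrlVehLPS). Ly86 was lower by a log2 fold change of -0.99 ± 0.15 (adjusted p = 0.00381), at 7.06 ± 0.985 CPM (SD, n = 4) against 14.0 ± 0.102 CPM (SD, n = 3), and Gcnt1, a glycosyltransferase of selectin ligands, by -1.03 ± 0.21 (adjusted p = 0.0398). Selp had 48 counts over CtrlVehLPS and 1 over GWCBD30LPS, a ratio of 74.0 with a 95% exact counting interval of 12.7 to 2981 (adjusted p = 0.00750), and Gm9522 had 37 and 1, a ratio of 57.0 with an interval of 9.62 to 2312 (adjusted p = 0.0398). In all 14 genes passed, 0 higher and 14 lower, and 1248 had an unadjusted p under 0.05. Of the 14, 9 were among the 83 raised by LPS in control mice (0.0580 by chance), a contrast that shares the CtrlVehLPS libraries. Endothelial activation and acute-phase genes (mean -0.86, adjusted p = 6.63e-14, 1 of 25 and 9 adjusted over the list alone), homeostatic microglia genes (mean -0.24, adjusted p = 3.71e-12, 1 of 21 and 10 adjusted over the list alone), heat shock genes (mean -0.20, adjusted p = 6.37e-13, 0 of 27 and 10 adjusted over the list alone) and glucocorticoid-responsive genes (mean -0.30, adjusted p = 5.24e-11, 0 of 20 and 8 adjusted over the list alone) were lower. So were olfactory bulb neuron genes (mean -1.17, adjusted p = 1.90e-11, 0 of 13 and 9 adjusted over the list alone), the group in which CtrlVehLPS stood apart. Among single members, Olfml3 passed (-0.60 ± 0.12, adjusted p = 0.0398) while Calr (-0.28 ± 0.06, adjusted p = 0.0846), Hif3a (-1.08 ± 0.24, adjusted p = 0.110) and Meis2 (-0.43 ± 0.11, adjusted p = 0.210) did not. The 14 calls became 5, 6 and 27 without CtrlVehLPS replicate 1, 2 and 3, and 0, 8, 2 and 6 without GWCBD30LPS replicate 1, 2, 3 and 4. With bulb and cerebellar scores as covariates 15 genes passed, of which 2 were among the 14. Selp was kept, while Ly86 (-0.83, adjusted p = 0.185), Olfml3 (-0.66, adjusted p = 0.185), Gcnt1 (-0.60, adjusted p = 0.789) and Gm9522 (adjusted p = 0.221) lost their call.

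Without LPS, exposed CBD mice and unexposed mice differed in 0 genes by edgeR (GWCBD30 against CtrlVeh), with 620 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma voom, and 1 without CtrlVeh replicate 2. The smallest p belonged to Tsc22d3 (-0.31 ± 0.07), Gm28437 (-2.07 ± 0.44) and Pbld2 (1.31 ± 0.36), each with an adjusted p of 1.0.

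The 99 genes called in control mice were followed in the other arms as a sign-weighted mean log2 CPM per library. With LPS this score rose by 0.32 in exposed vehicle mice, from 3.05 ± 0.0681 to 3.37 ± 0.0561, and by 0.16 in exposed CBD mice, from 3.00 ± 0.0640 to 3.16 ± 0.0256 (SD, n = 4 each, exact permutation p = 0.0286 for each, the smallest these groups allow, Benjamini-Hochberg adjusted 0.0381). Under LPS it was lower with CBD than with vehicle by -0.21 (exact permutation p = 0.0286). The difference between the LPS rises was -0.16 (exact permutation p = 0.102). Slopes of the fold changes of these genes on those in control mice were 0.473 in exposed vehicle and 0.200 in exposed CBD mice, a ratio of 0.424. That ratio was 1.32 without CtrlVehLPS replicate 3 and -0.00995 without GWCBD30LPS replicate 4, which had a raised olfactory bulb score, and 4 of the 99 genes are in the olfactory bulb list. The slopes themselves, on genes chosen anew in each fit, were 0.115 and 0.0586 without CtrlVehLPS replicate 2, 0.0695 and 0.0916 without CtrlVehLPS replicate 3, and 0.416 and -0.00414 without GWCBD30LPS replicate 4. Across the 20026 genes, which are not independent replicates, the LPS fold changes correlated with a Pearson r of 0.196 (Spearman 0.125) between control and exposed vehicle mice, 0.118 (0.231) between control and exposed CBD mice and 0.119 (0.172) between the exposed arms. Over the 11160 genes with an average log2 CPM of at least 3 the Pearson r was 0.172, 0.427 and 0.271 in that order, so the ranking of the pairs depends on the genes taken.

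Whether CBD shifted genes opposite to exposure was examined across genes. Under LPS, the fold changes for exposure and for CBD had r = -0.467, but both contrasts use the GWVehLPS libraries, and simulated unchanged groups gave -0.454 on average (-0.477 to -0.432 in 100 simulations). The covariance was -0.0432 against a simulated -0.0304 (-0.0325 to -0.0287), a difference of -0.0128. With the 4 shared libraries split 2 and 2, the mean r of the splits was -0.0627. Without LPS r was -0.520, against a simulated -0.461 (-0.482 to -0.436), with a covariance of -0.0375 against -0.0306, a difference of -0.00698, and a mean r of -0.0657 over the splits.

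Of the leading genes, on GRCm38 with GENCODE M21 gene bounds, C1qa (ENSMUSG00000036887) lies on chromosome 4 from 136895917 to 136898803, C1qb (ENSMUSG00000036905) from 136880129 to 136886187 and C1qc (ENSMUSG00000036896) from 136889804 to 136893065, all on the minus strand. Ly86 (ENSMUSG00000021423) spans 37345208 to 37419036 on chromosome 13. Olfml3 (ENSMUSG00000027848) lies on chromosome 3 from 103722222 to 103738001, Icam1 (ENSMUSG00000037405) on chromosome 9 from 21015985 to 21028817 and Lcn2 (ENSMUSG00000026822) on chromosome 2 from 32384633 to 32388252. Tsc22d3 (ENSMUSG00000031431) is on chromosome X from 140539528 to 140600659, Sox9 (ENSMUSG00000000567) on chromosome 11 from 112782224 to 112787760, and Selp (ENSMUSG00000026580) and Fcgr4 (ENSMUSG00000059089) on chromosome 1 from 164115264 to 164150026 and from 171018920 to 171029761. All are protein-coding, and Fcgr3 and Fcgr4, members of a family of similar genes, share the uncertainty of reads that match more than 1 copy.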

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

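The tests of the 3 patterns below were chosen only after the result was seen, while the counts over other splits of the samples were planned.

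The LPS response differed between exposed mice given CBD and exposed mice given vehicle in 9 genes, and in 7 gene lists that held with an estimated correlation, by the interaction test, which is what brought it here. Icam1, C1qa, Ifitm3 and Olfml3 were among the genes, and endothelial activation, interferon-stimulated, homeostatic microglia and complement genes among the lists. The make-up of the tissue in olfactory bulb and cerebellum is argued against as the whole cause, since 48 of the 48 genes that differed between CBD and vehicle under LPS still passed with both scores in the model, and a single library by the endothelial activation list, whose mean log2 fold change of -1.21 was -1.01 at its nearest to 0 when 1 of the 8 libraries was left out. Choroid plexus content stays open, since 31 of the 48 genes, and 6 of the 9, passed with its score in the model. An absent LPS response in the CBD mice is argued against by the score of the 99 genes called in control mice, which was 0.16 higher in GWCBD30LPS, with all 4 libraries above all 4 of GWCBD30 (exact permutation, Benjamini-Hochberg adjusted p = 0.0381), although the endothelial activation and cytokine scores changed by -0.06 and -0.06. A lower effective LPS exposure cannot be told apart from a weaker response to the same exposure, since both would give the ratio of 0.437 between the rises of the microglia score and no measure of exposure was used here.

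Of the 13 olfactory bulb neuron genes, 10 were higher in all 3 CtrlVehLPS libraries than in all 3 CtrlVeh libraries. For a single gene chance gives 5%, but members move together and the list was singled out for this rise, so the count restates the pattern. More bulb tissue in those samples stays open. A rise with LPS in all mice is argued against by the other arms, where 5 of 8 LPS libraries did not score above their arm's PBS libraries. Scores of 2.69 to 3.64 occurred only with LPS, against at most 2.18 with PBS. LPS effects in some mice, or only in unexposed ones, were not tested.

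CtrlVehLPS replicate 1 lacked cerebellar transcripts and held transcripts of pancreatic enzymes. In it 11 of 16 cerebellar genes lay under 25% of their mean in the other libraries, and 16 of 18 acinar enzyme genes lay over 10 times their highest value elsewhere. Examples are Cela1 (63.7 CPM against at most 3.76 elsewhere), Ctrb1 (46.3 against 0.214) and Pnlip (34.8 against 1.06). LPS as the cause of the enzyme transcripts is argued against by the other CtrlVehLPS libraries, whose highest sum was 7.60 CPM against 398.5 CPM. A sample without most of the cerebellum and with RNA of pancreas is a candidate explanation that these counts restate and do not decide, and no other biological explanation was tested.

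Other splits of the same samples were counted to see how often they give as many genes as the real one. For LPS in exposed vehicle mice the 188 genes were reached by 1 of 35 splits, the real one (highest other 10). For CBD against vehicle under LPS the 48 genes were also reached by 1 of 35 (highest other 2). That share is the smallest that 35 splits allow and was not adjusted over the 11 contrasts. It argues against chance for these counts without excluding it. For exposed CBD mice against controls under LPS the 14 genes were reached by 1 of 35 splits (highest other 0), but the count was 0 without GWCBD30LPS replicate 1, 2 without GWCBD30LPS replicate 3 and 1 with the strict filter. With bulb and cerebellar scores in the model 2 of the 14 passed. For the interaction of CBD and LPS the 9 genes were reached by 2 of 60 splits, a share under 0.05, but the other of these gave 13 and parted the LPS libraries as the study did, and the count was 2 without GWCBD30 replicate 1. For LPS in exposed CBD mice the count of 1 gene was reached by 1 of 35 splits, the real one (highest other 0), but that call was lost without GWCBD30 replicate 1 or 3 or GWCBD30LPS replicate 2 or 4. For LPS in control mice the 10 splits are too few for a share under 0.05, with 99 genes in the real split and 0 as the highest other. For exposure under LPS the 1 gene was reached by 8 of 35 splits (highest other 26), so the splits do not argue against chance. For the edgeR counts of 0 every split reaches the count by construction, so the splits decide nothing: exposure without LPS (35 of 35, highest other 50, with 1762 genes at an unadjusted p under 0.05, 6 by DESeq2 and 176 by limma voom), CBD without LPS (35 of 35, highest other 2, with 1288, 0 and 0), exposed CBD mice against controls without LPS (35 of 35, highest other 0, with 620, 1 and 0) and the interaction of exposure and LPS (60 of 60, highest other 1, with 1688, 28 and 0). The split with 50 genes, which set GWVeh replicate 4 with the CtrlVeh libraries, and the split with 26 call more than the real counts of 0 and 1, which points to a structure of the samples that was not tested. In GWVeh replicate 4 the serotonin neuron gene Tph2 was at 1.84 CPM, against 3.70 to 7.41 CPM in CtrlVeh and 19.2, 19.7 and 5.68 CPM in GWVeh replicates 1, 2 and 3.

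Single libraries lay far from the rest of their group in 8 of 176 tests, where chance gives 8.8. The score of the 99 genes was 2.95 in GWVeh replicate 4 (others 3.07 to 3.10) and 3.29 in GWVehLPS replicate 4 (others 3.39 to 3.40). The score of NRF2 and antioxidant genes was 5.46 in GWCBD30 replicate 4 (others 5.58 to 5.60). Cholinergic signalling genes scored 3.83 in GWVehLPS replicate 1 (others 3.94 to 3.95) and 3.74 in GWCBD30 replicate 4 (others 3.83 to 3.85). In GWCBD30LPS replicate 3 the endocannabinoid score was 4.34 (others 4.43 to 4.45) and the oligodendrocyte score 6.86 (others 6.71 to 6.73). The red blood cell score was 4.45 in GWCBD30LPS replicate 4 (others 3.95 to 3.96).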

How the results depend on the processing

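The olfactory bulb and cerebellar covariates, and the removal of CtrlVehLPS replicate 1 from contrasts that do not hold it, were chosen only after the result was seen; the other alternatives were planned. For changes of a count or a direction the cause was not tested, except where the text below says that it follows from the alternative itself.

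RLE scaling kept all 14 counts and ratios within 1.5 times. Upper-quartile scaling moved LPS in exposed CBD mice from 1 gene to 3. Without a filter on low counts, LPS gave 357 genes in control, 359 in exposed vehicle and 64 in exposed CBD mice. Exposure gave 36 without and 118 with LPS, CBD under LPS 138, exposed CBD mice against controls 1 without and 95 with LPS, and the interactions 82 (exposure) and 37 (CBD). The strict filter left 1 gene between exposed CBD mice and controls under LPS.

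DESeq2 gave 269, 320 and 38 genes for LPS in control, exposed vehicle and exposed CBD mice, 6 and 25 for exposure without and with LPS, 108 for CBD under LPS, 1 and 47 for exposed CBD mice against controls without and with LPS, and 28 and 24 for the interactions. Limma voom gave 694, 293 and 87 for LPS in the same order, 176 and 5 for exposure, 158 for CBD under LPS, 206 for exposed CBD mice against controls under LPS and 42 for the interaction of CBD and LPS. Fitting only the groups of a contrast, which changed both the samples and the genes tested, gave 57 for LPS in control and 13 in exposed CBD mice, 2 for exposure under LPS and 1 for exposed CBD mice against controls without LPS. An adjusted p of 0.1, a looser threshold from which a higher count follows, gave 247, 313 and 21 for LPS, 9 for exposure under LPS, 73 for CBD under LPS, 23 for exposed CBD mice against controls under LPS and 21 for the interaction of CBD and LPS.

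With 1 surrogate variable, LPS gave 331 genes in control and 14 in exposed CBD mice, exposure without LPS 3, exposed CBD mice against controls under LPS 37 and the interaction of CBD and LPS 20. The choroid plexus covariate gave 11 for LPS in exposed CBD mice, 0 for exposure under LPS and 6 for exposed CBD mice against controls under LPS. The bulb and cerebellar covariates gave 32 for LPS in control mice (21 of the 99), 18 in exposed CBD mice, 0 for exposure under LPS, 80 for CBD under LPS (all 48 included) and 17 for the interaction of CBD and LPS. They reversed the bulb list for LPS in exposed vehicle mice (-0.14) and for exposed CBD mice against controls under LPS (0.10), and in these contrasts S100a5 (-0.87) and Scgn (0.23), which follows from a covariate built from that list. The mean of the endocannabinoid list for CBD under LPS, 0.01 as reported and not past the threshold, was -0.0192 with these covariates and -0.0122 with 1 surrogate variable. With 1 library left out it ran from -0.0376 (without GWCBD30LPS replicate 1) to 0.0433 (without GWCBD30LPS replicate 3), and was -0.0273 without GWVehLPS replicate 3 and -0.00110 without GWCBD30LPS replicate 2.

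The replicate numbers did not clearly pair the samples. Over 51 pairs with the same number, deviations from group means correlated at 0.0102 on average, against -0.00342 for other pairs. However, 10 of 22 libraries correlated best with a library of their own number, so a partial pairing stays open. A replicate block gave 16 genes for LPS in exposed CBD mice, 9 for exposure without LPS, 9 for exposure with LPS, 6 for exposed CBD mice against controls under LPS and 15 for the interaction of CBD and LPS.

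Leaving out 1 library gave 20 to 132 genes for LPS in control mice, 125 to 266 in exposed vehicle mice and 0 to 13 in exposed CBD mice. Exposure gave 0 to 12 without and 0 to 24 with LPS, CBD 0 to 0 without and 22 to 67 with LPS, and exposed CBD mice against controls 0 to 1 without and 0 to 27 with LPS. The interactions gave 0 to 3 (exposure) and 2 to 17 (CBD). The slope ratio of the 99 genes ran from -0.00995, a reversal without GWCBD30LPS replicate 4, to 1.32. With the shared libraries split 2 and 2, so that the contrasts share no library, the correlation of exposure and CBD effects was -0.0627 with LPS and -0.0657 without. Without that split, for genes with an average log2 CPM of at least 3, it was -0.707 without LPS, a setting in which the GWVeh libraries are shared and for which unchanged groups were not simulated.

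Of 78 lists described, 78 kept direction and side of the threshold with RLE scaling and 78 with the strict filter, and 32 lost their call with an estimated correlation and 28 with fry. Of 673 list results with 1 library left out, 659 kept both. Of 278 named gene results, 278 kept both with RLE scaling and 276 with upper-quartile factors, while 26 lost their call with the choroid plexus covariate and 23 with the bulb and cerebellar covariates. Fitting only the groups of a contrast lost 33 of 270, and leaving out 1 library lost 297 of 2367. Calls of genes picked by the naming rule that were kept whichever library was left out were 7 of 28 for LPS in control mice, 26 of 46 in exposed vehicle mice, 16 of 28 for CBD under LPS and 0 of 5 for exposed CBD mice against controls under LPS. They were 0 of 6 for the interaction of CBD and LPS, where 6 of the 9 called genes were picked by the rule, 0 of 1 for LPS in exposed CBD mice and 0 of 1 for exposure under LPS. In the shallowest library, 3 counts correspond to 0.175 CPM, which limits genes such as Selp and Sele.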

Other observations

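In control mice, the gene of the main brain cannabinoid receptor, Cnr1, was lower with LPS by a log2 fold change of -0.41 ± 0.09 (adjusted p = 0.0317, edgeR), at 221 ± 8.66 CPM in CtrlVeh and 167 ± 23.6 CPM in CtrlVehLPS (SD, n = 3 each). Its call was lost without CtrlVeh replicate 1, 2 or 3 (adjusted p = 0.0994, 0.186 and 0.0910) or CtrlVehLPS replicate 1 (adjusted p = 0.160). It was also lost with olfactory bulb and cerebellar scores as covariates (adjusted p = 0.573), a test chosen after the result was seen. The endocannabinoid system and cannabidiol target list had a mean of 0.11 in this contrast (adjusted p = 0.0662), with 0 of 28 members higher and 1 lower over all genes, and 1 higher and 1 lower adjusted over the list alone. The list's adjusted p was 0.0416 without CtrlVeh replicate 3, 0.0336 without CtrlVehLPS replicate 2 and 0.0176 without CtrlVehLPS replicate 3. Ppara, a nuclear receptor for fatty acid amides (0.89 ± 0.26, adjusted p = 0.121), and the serotonin receptor gene Htr1a (0.36 ± 0.13, adjusted p = 0.222) did not pass.

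Gapdh, a glycolytic enzyme gene with many near-identical pseudogenes, was listed at 10.0 to 14.9 CPM in 18 libraries. It was at 99.2 CPM in CtrlVehLPS replicate 1, 179 CPM in GWVeh replicate 2, 52.5 CPM in GWCBD30 replicate 1 and 160 CPM in GWCBD30LPS replicate 3, so these libraries come from 4 groups. Gm28437 was at 286 and 177 CPM in CtrlVeh replicates 1 and 3 and at 32.0 to 68.0 CPM in the other 20 libraries.

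Tph2 and Slc6a4, genes of the serotonin neurons of the raphe, varied between libraries and were looked at after the result was seen. Tph2 was at 3.70, 4.93 and 7.41 CPM in CtrlVeh and 10.6, 17.3 and 18.0 CPM in CtrlVehLPS. It was at 19.2, 19.7, 5.68 and 1.84 CPM in GWVeh replicates 1 to 4, 15.3, 15.2, 11.1 and 1.32 CPM in GWCBD30 replicates 1 to 4, 15.4 to 21.1 CPM in GWVehLPS and 13.8 to 16.7 CPM in GWCBD30LPS. Slc6a4 was lowest in the same 2 libraries, GWVeh replicate 4 (0.743 CPM) and GWCBD30 replicate 4 (0.658 CPM).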
